A study of Homo sapiens
Mus musculus and Drosophila melanogaster
Mus musculus with 154 samples.

How the data were processed

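The study used spike-in calibrated chromatin immunoprecipitation sequencing (ChIP-seq), in which cells of another species are added to each sample so that signal can be scaled between samples. Per the labels, the spike-in cells were Drosophila SG4 cells or human HEK293T cells, an established human embryonic kidney line. The labels describe 154 samples in 50 groups, from 4 mouse embryonic stem cell lines. They comprise 96 immunoprecipitations with 8 antibodies and 58 inputs. Every immunoprecipitation group has 3 samples. Samples were grouped by line, antibody or input type, and treatment, as their titles give them. 4 native input groups of the PRC1deg line have 4 samples, because 1 replicate number occurs there on more than 1 input.

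Values were taken from 1 processed file, a list of RING1B peaks with 3 columns: chromosome, start and end. The deposited list gives genomic positions in base pairs and holds no height, fold enrichment, p-value or score per peak. The submitters' processing notes name Bowtie2, deepTools and MACS2, and the builds mm10, dm6 and hg19, without a role for any of them. Which RING1B libraries went into the list, the settings and threshold of the caller, how replicates were combined, and any removal of regions afterwards are not given in the sources used here. The list was treated as a pooled result of the whole series, so no replicate error and no n belongs to any value from it. The depth behind the peaks is unknown. A caller's threshold keeps weak binding out of such a list, and its rule for joining neighbouring signal sets the width and the number of peaks.

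The build was checked against chromosome lengths from the R package GenomeInfoDb 1.38.1 (R 4.3.3). On mm10, 0 peaks ended past the end of a chromosome, against 22 on mm9 and 4 on mm39. All positions are mm10, with starts counted from 1. 0 peaks overlapped another peak, and no filter was applied.

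Width was summarised by the median and quartiles, with a 95% interval of the median from binomial order statistics. Peak counts per chromosome were compared with the chromosome's share of the summed length of the 20 chromosomes in the list. A chi-square goodness-of-fit test covered the 20 chromosomes together. An exact two-sided binomial test with a Clopper-Pearson 95% interval covered each chromosome, with Benjamini-Hochberg adjustment over the 20 chromosomes and a threshold of 0.05. Closeness of peaks was measured as the share of peaks with another peak within 10 kb, edge to edge. It was compared, two-sided, with 1000 random placements of the same widths on the same chromosomes without overlap. The smallest p that 1000 placements can give is 0.001. Median widths of 2 sets of peaks were compared by a two-sided permutation test with 100000 permutations, whose smallest p is 1e-05, and 4 such comparisons were adjusted together. These tests treat peaks as independent, and random placement is uniform along a chromosome, so gene density, assembly gaps and mappability are not taken into account. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

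The tests were tried on simulated lists of 7240 peaks, 100 lists per setting with 99 placements each. With random placement, closeness was called at p under 0.05 in 6 of 100 lists and the X chromosome in 0. With 200 added close pairs, closeness was called in 100 of 100. With X density set to 0.8 of the other chromosomes, the X chromosome was called in 95 of 100. A width difference of 1.2-fold was called in 99 of 100 lists, and with no difference set, 4 of 100 were called. Apart from the set differences, the simulated lists were spread uniformly, as the tests assume. They therefore give no error rate for a list of uneven density.

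The design and its alternatives were fixed before the data were examined: peaks joined over gaps of up to 1 kb, only the wider 50% of peaks (the list holds no score to rank by), covered bases in place of counts, and neighbours within 5 kb or 50 kb. Alternatives chosen after seeing the data were peaks joined over gaps of up to 3 kb, groups of peaks counted once, autosomes only, placement between the first and the last peak of a chromosome, and placement inside 1 Mb windows, alone or followed by joining over 3 kb. Placement inside windows let peaks overlap, and without joining an overlapping peak counted as a neighbour. To see what low density alone gives, the X peaks were also placed at random over the X chromosome 1000 times. The rule for regions given singly was the 10 widest peaks and the 3 groups with the most peaks, where a group is formed by peaks joined over gaps of up to 10 kb. That rule names genes only with an annotation of mm10. No such annotation or genome sequence was used here, so no gene is named. Overlap with promoters, sequence content and tests of gene lists were not analysed here. Comparisons between treatments, lines and antibodies were not analysed here either, because they need values per sample.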

Results

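RING1B is a catalytic subunit of Polycomb repressive complex 1 (PRC1), which places ubiquitin on histone H2A. SUZ12 is a core subunit of PRC2, which methylates lysine 27 of histone H3. Both complexes act in gene repression. The PRC1deg line of mouse embryonic stem cells is a knockout for RING1A, the related catalytic subunit, and its RING1B carries an auxin-inducible degron, a tag that leads to degradation of the protein once auxin is added. In the PRC2deg line, SUZ12 carries a degron that responds to the compound dTAG-13. The lines labelled as wild-type controls were E14 and TIR1. PRC1deg cells received 500 µM auxin for 2, 4, 8 or 24 h, and PRC2deg cells 100 nM dTAG-13 for 2 h.

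Immunoprecipitated chromatin was sequenced from 96 samples. SUZ12 was profiled in 15 of them, RING1B in 12, histone H3 trimethylated at lysine 27 (H3K27me3) in 24, monoubiquitinated histone H2A (H2AK119ub1) in 9 and H3K4me3, a mark of active promoters, in 12. RNA polymerase II was profiled with an antibody to its N-terminal domain in 12 samples, and in its forms phosphorylated at serine 5 or serine 2 of the C-terminal domain in 6 samples each. The 12 RING1B samples came from untreated TIR1 cells, untreated PRC1deg cells and PRC1deg cells after 2 or 4 h of auxin, with 3 samples each. The design asks how each of these signals changed after degradation of RING1B in cells without RING1A, how H3K27me3 changed after degradation of SUZ12, and whether the degron lines differed from wild type before treatment, in RING1B for PRC1deg and in H3K27me3 for PRC2deg. Those comparisons were not analysed here. The values below describe where RING1B was found, from a single list of peaks without replicate errors. The depth behind the list is unknown.

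RING1B occupied 7240 regions on the 19 autosomes and the X chromosome. Together they covered 16.7 Mb, or 0.635% of the length of these chromosomes. Most regions were short. The median width was 1562.5 bp, with a 95% interval of 1533 to 1595 bp, and the quartiles were 972 bp and 2618 bp. Of all peaks, 1921 (26.5%) were under 1 kb wide. The narrower 50% of the peaks held 21.1% of the covered bases, and the widest 10% held 35.4%. Peaks of 10 kb or more numbered 165 (2.28% of the list), and they held 15.3% of the covered bases.

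**Figure D1:**
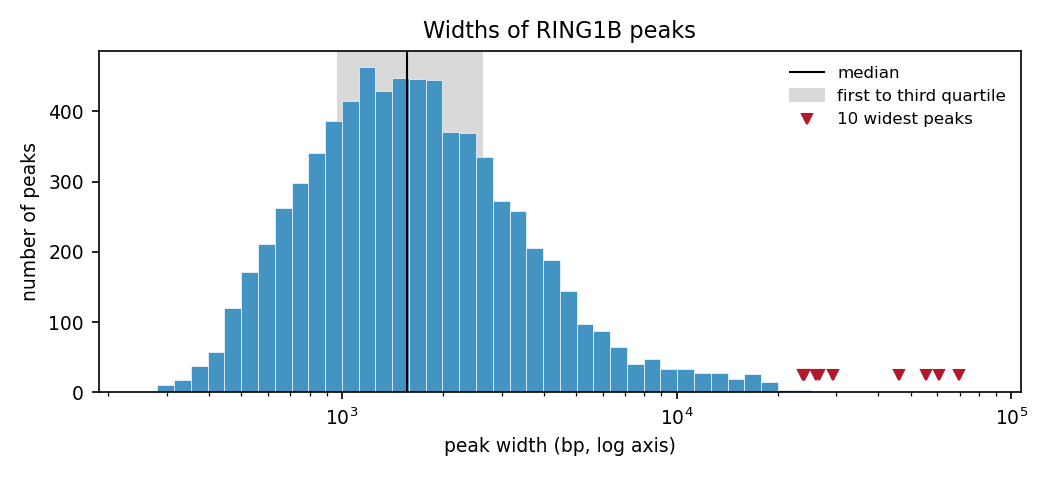
Number of RING1B peaks (vertical axis) by width in bp (horizontal log axis), with the median as a line, the range from the first to the third quartile in grey and the 10 widest peaks as triangles. The median is 1562.5 bp, and 4 peaks lie apart at 45966 bp or more.

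The widest RING1B peaks stood apart from the rest of the list. A set of 4 peaks was over 40 kb wide, and the next in order was 29266 bp. The widest lay on chromosome 6 at 52197054 to 52266931 and measured 69878 bp, 44.7 times the median. The second lay on chromosome 2 at 74654400 to 74715309 (60910 bp), the third on chromosome 15 at 102947661 to 103003384 (55724 bp) and the fourth on chromosome 11 at 96275579 to 96321544 (45966 bp). These 4 peaks held 1.39% of all covered bases. Each of them had another peak within 10 kb, at distances of 3468, 8480, 1461 and 967 bp.

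The other six of the 10 widest peaks measured between 23795 and 29266 bp. They lay on chromosome 14 at 122462689 to 122491954, chromosome 11 at 119034012 to 119060601, chromosome 2 at 105665311 to 105691436 and at 38335822 to 38359814, chromosome 5 at 139535280 to 139559203, and chromosome 19 at 44739001 to 44762795. Of these, the peaks on chromosome 5 and at 38335822 on chromosome 2 were isolated, with the nearest other peak 176.7 kb and 348.1 kb away. No gene is named at these positions, since an annotation of mm10 was not used here.

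Neighbouring RING1B peaks formed 467 groups of at least 2 peaks with gaps of up to 10 kb, and these held 1075 peaks. The remaining 6165 peaks stood alone. Most groups were pairs (370), and 7 groups had 5 or more peaks. The group with the most peaks lay on chromosome 15 at 102909388 to 103036013, with 9 peaks that covered 73.2% of its 126.6 kb, the third widest peak among them. Second was a group of 8 peaks on chromosome 18 at 37714790 to 37768708, which covered 61.5% of 53.9 kb. Its widest member measured 16148 bp. Groups of 7 peaks lay on chromosome 11 at 96269389 to 96375302, with 80.5% of 105.9 kb covered, and on chromosome 8 at 105253722 to 105291114, with 42.8% of 37.4 kb covered. The group on chromosome 8 had no member wider than 5112 bp. The widest and second widest peaks of the list each belonged to a group of 5, on chromosome 6 at 52156797 to 52275839 and on chromosome 2 at 74654400 to 74764980, which were 83.2% and 81.6% covered.

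**Figure D2:**
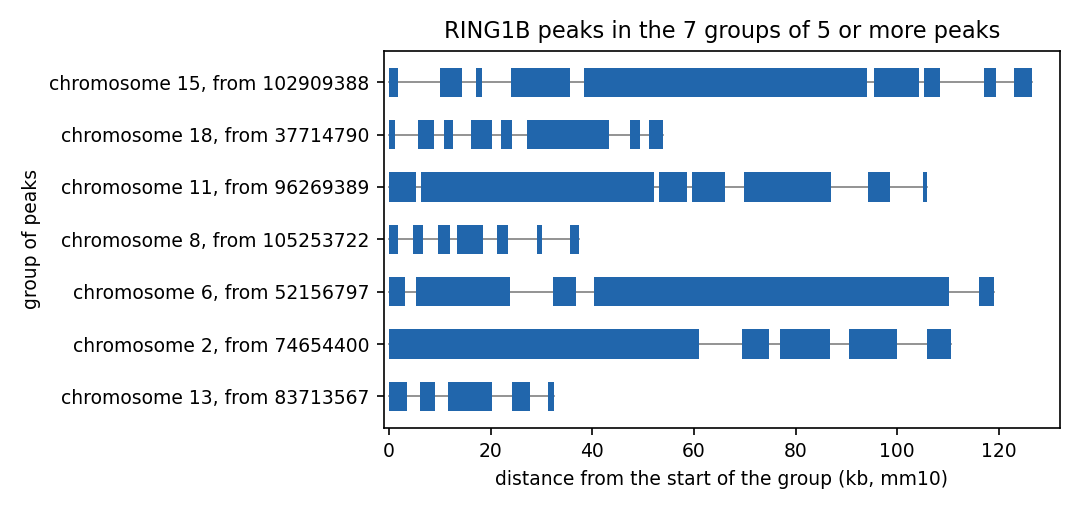
RING1B peaks (blue bars, to scale) in the 7 groups of 5 or more peaks, with distance from the start of each group in kb on the horizontal axis and the chromosome and mm10 start of the group on the vertical axis. The groups on chromosomes 15, 11, 6 and 2 each hold 1 peak of over 40 kb, whereas no peak of the group on chromosome 8 exceeds 5112 bp.

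RING1B peaks were closer together than random placement gave. Of the 7240 peaks, 1075 (14.8%) had another peak within 10 kb. In 1000 random placements the share averaged 5.83%, and the central 95% of placements ran from 5.07% to 6.55%. The observed share was 2.55 times the random mean (two-sided permutation p = 0.001, the smallest that 1000 placements can give). The excess was 2.89-fold at 5 kb, where 8.58% of peaks had a neighbour against 2.96%. At 50 kb it was 1.66-fold, with 42.9% against 25.8%. When each peak was placed at random inside its own 1 Mb window, a setting chosen after seeing the data, the random mean rose to 13.03% and the ratio fell to 1.14 (permutation p = 0.001). Unlike the peaks of the list, peaks placed in this way could overlap, and overlapping peaks counted as neighbours. That raises the random share. Placement was also uniform inside each window, without regard to gene density, assembly gaps or mappability, which can lower the random share. The ratio of 1.14 may therefore be too low or too high.

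**Figure D3:**
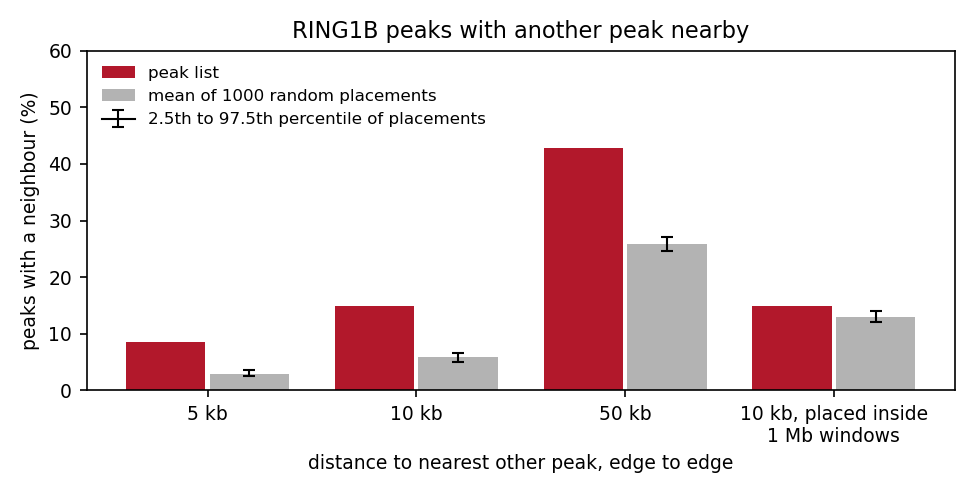
Share of RING1B peaks in percent (vertical axis) with another peak within 5, 10 or 50 kb edge to edge, in the list (red) and as the mean of 1000 random placements (grey), with bars over the central 95% of the placements. The list lies above the placements in each pair, and least so, at 14.8% against 13.03%, when peaks were placed inside their own 1 Mb windows. Only in that last pair could placed peaks overlap, which raises the random share. Uniform placement inside a window can also lower it.

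The X chromosome held few RING1B peaks for its length. It held 1.70% of the peaks and 6.49% of the length, a ratio of 0.262 with an exact 95% interval of 0.218 to 0.312 (exact binomial test, adjusted p = 2.07e-83). This was 0.719 peaks per Mb, against 2.89 per Mb over all autosomes, a 4.02-fold difference. Peaks covered 0.170% of the X chromosome and between 0.427% (chromosome 16) and 1.10% (chromosome 11) of each autosome.

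Autosomes also differed from one another, by up to 2.39-fold. Chromosome 11 had the highest density for its length, with 562 peaks and a ratio of 1.67 (1.54 to 1.81, adjusted p = 4.46e-30 by the exact binomial test). Chromosome 19 followed with 258 peaks and a ratio of 1.53 (1.35 to 1.72, adjusted p = 7.4e-10, exact binomial test). The lowest autosomal ratios were 0.702 on chromosome 14 (0.617 to 0.795, adjusted p = 1.55e-08, exact binomial test), 0.737 on chromosome 16 (0.639 to 0.845) and 0.771 on chromosome 3 (0.692 to 0.855). In all, 10 chromosomes had more peaks than their length gave, 6 had fewer and 4 did not pass the test (chi-square = 648.5 with 19 degrees of freedom, p = 2.92e-125). The expectation includes the X chromosome, whose few peaks raise the ratio of each autosome. Among the autosomes alone, an alternative chosen after seeing the data, 7 had more peaks than their length gave (chromosomes 2, 4, 7, 8, 9, 11 and 19) and 8 had fewer (chromosomes 1, 3, 6, 12, 13, 14, 16 and 18). Because neighbouring peaks are not independent, these p-values are too small. With only the wider 50% of the peaks, 6 chromosomes passed in place of 16: chromosomes 2, 11 and 19 with more peaks, and chromosomes 14, 16 and X with fewer. The 10 chromosomes that lost their call all kept their side of 1, and the test had fewer peaks to work on. Their ratios moved closer to 1 on 9 of them, as on chromosome 7 (1.26 to 1.16) and chromosome 4 (1.16 to 1.04), and further from 1 on chromosome 15 (1.13 to 1.18).

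**Figure D4:**
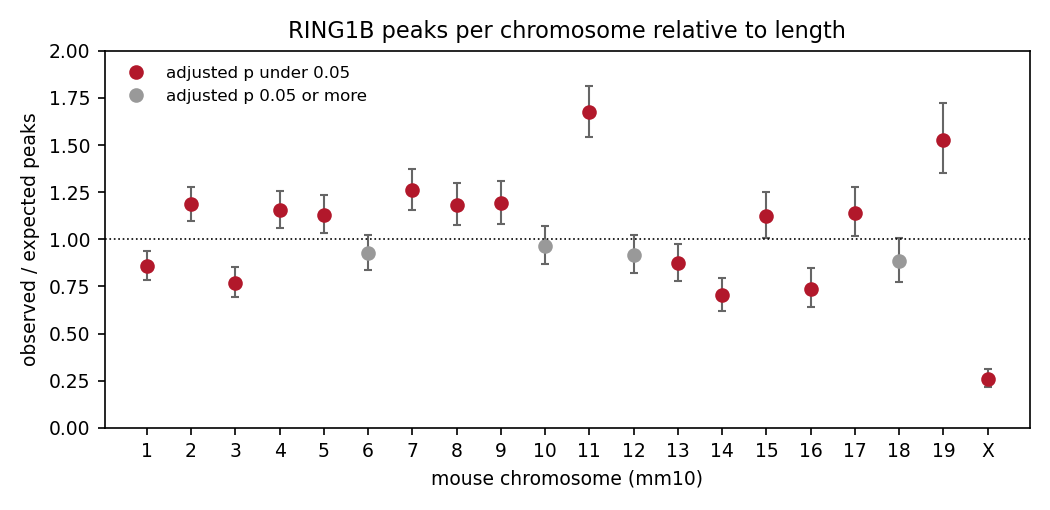
Ratio of observed to expected RING1B peaks (vertical axis) for each mouse chromosome (horizontal axis), where the expectation follows chromosome length, with exact binomial 95% intervals as bars and chromosomes past an adjusted p of 0.05 in red. The X chromosome lies at 0.262, below all autosomes, which range from 0.702 to 1.67.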

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

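Joining peaks over gaps of 10 kb or 3 kb, leaving out the X chromosome, and placement between the first and last peak or inside 1 Mb windows (also with joining over 3 kb) were chosen after seeing the data. The share of peaks with a neighbour stayed above random placement under all 8 alternatives run for it, each with a permutation p of 0.001. The X ratio stayed below 1 in all 3 of its alternatives, from 0.267 to 0.306. With the wider 50% of peaks, 3620 peaks were left with a median width of 2618 bp, by construction, and 6 chromosomes passed the test in place of 16, in part because fewer peaks entered it. These 6 were also called, in the same direction, with all peaks. Counting groups once called 15 chromosomes, all shared. Without the X chromosome 15 autosomes were called, 7 above and 8 below their length, 12 of them shared. Chromosomes 5, 15 and 17 lost their call above (adjusted p = 0.119, 0.205 and 0.156, exact binomial test), and 6, 12 and 18 were newly called below (0.0171, 0.0194 and 0.0170), because the expectation no longer holds the X chromosome. By covered bases, which were given no interval or test, chromosome 13 moved from 0.873 to 1.00, level with its length. Chromosome 2 moved from 1.18 to 1.33, chromosome 4 from 1.16 to 1.05 and chromosome 7 from 1.26 to 1.11. The cause of these shifts was not tested. Joining over 1 kb left 7202 peaks and a median of 1561 bp. The list gives no depth, so how many weak sites stayed under the caller's threshold is unknown. No paired analysis was possible because the peak list has no values per sample. For the same reason, leaving out each replicate was not run. Alternatives for promoters, sequence content and gene lists were not run, since they need the mm10 sequence and annotation.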

Other observations

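The tests of windows, position along the chromosome, widths and joined peaks in this part were chosen only after the peak list had been seen. RING1B peaks were concentrated in some 1 Mb windows. The densest held 29 peaks, on chromosome 8 from 70000001 to 71000000, followed by 27 peaks on chromosome 10 from 80000001 to 81000000 and 23 on chromosome 18 from 37000001 to 38000000. Windows with 22 peaks lay on chromosome 11 from 120000001 and on chromosome 7 from 19000001. In 1000 random placements no window held more than 16. At the other end, 736 of 2645 windows (27.8%) held no peak, against a random mean of 9.45% and a random maximum of 11.2%. The 4 longest stretches without a peak between neighbouring peaks measured 14.7, 13.4, 12.6 and 12.2 Mb. The first 3 lay on the X chromosome, starting at 21361486, 120293155 and 73640609, and the fourth on chromosome 15 at 13176185 to 25412502.

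Peak density was also compared along chromosomes. Pooled over the list, 58.4% of peaks lay beyond the midpoint of their chromosome, toward higher coordinates, and the share ran from 36.2% on chromosome 17 to 80.7% on chromosome 15. More peaks lay beyond than before the midpoint on 13 of 20 chromosomes, which an exact two-sided sign test did not separate from chance (p = 0.263). The sign test asks only whether chromosomes share a direction. It does not ask whether peaks were spread evenly along a single chromosome.

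The low number of X-chromosomal peaks was weighed against 2 explanations, and neither could be settled. Once stretches of over 2 Mb without a peak were taken out of the length of all chromosomes, the X ratio was 0.610 (0.508 to 0.727), against 0.790 (0.710 to 0.876) on chromosome 3, the lowest autosome. The upper bound of 0.727 lay below 0.790, the limit set for deciding against the stretches. That limit was the autosome's value without its interval, and the intervals overlap. The same X peaks spread evenly at random already gave 0.440 (0.372 to 0.523), below the observed 0.610. Stretches of over 2 Mb without a peak took up 69.7% of the X length, against 57.1% (49.3% to 64.4%) under that spread. The stretches are also chosen by their lack of peaks, so removing them raises the ratio by construction. The test therefore decides neither for nor against them. A second candidate explanation is that a single-copy X chromosome loses weak peaks at the caller's threshold. The X density relative to autosomes was 0.275 (0.190 to 0.386) among peaks of at least 2616 bp and 0.249 among all peaks. The deficit thus remained among wide peaks. A weaker signal could also narrow X peaks, so an equal width limit cannot decide. X peaks had the higher median width (1853 against 1558 bp, permutation test, adjusted p = 0.032), which a loss of narrow peaks would also give. Autosomal medians ran from 1426 bp on chromosome 16 to 1855 bp on chromosome 18, so the X median lay within their range. A test that set X peaks of at least 1308 bp against autosomal peaks of at least 2616 bp gave 0.655 (0.518 to 0.818), but the unequal limits raise this value by construction, so it decides nothing. The explanation stays open because the list holds no peak heights, and the depth and the caller's threshold are unknown. Width stands in for strength by assumption. Gene and CpG island density along the X chromosome, a biological alternative, was not tested. Assembly gaps and mappability, which the expectation by length leaves out, were not tested either.

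The closeness of peaks was set against regional density and against the splitting of single domains by the caller. Random placement inside 1 Mb windows gave a share of 13.03% (12.07% to 13.96%), against 5.83% for uniform placement and 14.8% observed. Keeping the density of each window thus gave most of the excess over uniform placement. The remaining difference argues against density at the megabase scale as the whole cause. After peaks with gaps of up to 3 kb were joined, 10.3% of the joined peaks still had a neighbour within 10 kb, against 5.64% (4.95% to 6.35%) for uniform placement. Those placements were not joined again, so they count gaps of up to 3 kb that the joined list cannot hold. With peaks placed inside their 1 Mb windows and then joined in the same way, the share was 7.65% (6.84% to 8.49%), so density at that scale together with splits of up to 3 kb did not reach the observed share either. Gene density inside windows and longer splits stay open, and no biological explanation was tested, since the list holds no groups.

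Peaks with a neighbour within 10 kb were wider than the rest, with medians of 1864 and 1519 bp over 1075 and 6165 peaks (permutation test within chromosomes, adjusted p = 2e-05). Among the widest 1% of peaks 42.5% had such a neighbour (30.97% to 54.6%), against 11.4% in the narrowest 25% (9.95% to 12.9%). Measured from midpoint to midpoint within 20 kb, the difference was still 197.5 bp (adjusted p = 2e-05, permutation test). This measure works against wide peaks: without overlaps, a peak of over 40 kb cannot have such a neighbour. The size of the difference is therefore not free of width, but its direction argues against reach as the whole cause. Peaks whose nearest neighbour lay 10 to 50 kb away were not wider but had a lower median than more isolated peaks, by a difference of -127.5 bp (adjusted p = 0.00453, permutation test). A width difference limited to distances of up to 10 kb is consistent with broad domains that the caller divided into several peaks, as a hypothesis. A biological explanation was not tested. The tests and intervals of this paragraph treat peaks as independent, although members of a group are neighbours of one another. The p-values may therefore be too small and the intervals too narrow.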
